A study of Macaca mulatta and Chlorocebus aethiops with 88 samples.

How the data were processed

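Total RNA from bulk tissue samples of 2 cortical regions was sequenced after ribosomal RNA removal with a stranded library kit, per the labels' protocols. The 88 libraries came from 44 monkeys. African green monkeys (Chlorocebus aethiops) gave 19 prefrontal and 19 visual cortex libraries, and rhesus macaques (Macaca mulatta) gave 25 of each, with 1 library per region and animal. The labels name the prefrontal region dorsolateral in African green monkeys and dorsal in macaques. Age in weeks, sex, animal and batch were taken from the labels. Batch 1 held every African green monkey library and batch 2 every macaque library, so species and batch cannot be told apart in any level between species, and no such level was tested. Age slopes and region differences were measured within a species and therefore within a batch.

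A pair of tables covering all libraries was used. The first holds estimated counts per gene, which the authors made with RSEM, per the submitters' processing notes, which give no version. The second holds FPKM values for the same genes and libraries, deposited by the authors and named as FPKM per the file headers. The aligner, the genome build and the annotation are not given in the sources used here. Both tables list 63677 gene IDs of the ENSG form, and the FPKM column names carry the words human and RNA-Seq beside the cortex. How reads of 2 monkey species were assigned to these IDs is not given, so genes with near-identical copies, overlapping genes and genes that differ from the reference sequence are uncertain. The files do not pair the IDs with names. The name tables used here cover macaque genes, and 0 of the IDs matched, so genes are given by ID and no gene name or function is stated.

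Estimated counts were rounded to whole numbers. Library totals ran from 1089960 to 7380607 counts, and 32111 IDs had a count in at least 1 library. No pair of libraries was identical, and the closest pair within a group differed by a chi-square of at least 1.97 per degree of freedom, so every library was kept as a separate replicate. Each animal is a separate biological sample.

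The main tests were edgeR (version 4.0.16, R 4.3.3) quasi-likelihood F tests with robust dispersion, TMM factors and the filterByExpr filter at its default settings, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Age was fitted as a linear slope per 10 years, with sex as a covariate, in each of the 4 groups alone. The visual cortex was compared with the prefrontal cortex within animals, with the animal as a block, and calls were also counted at an absolute log2 fold change of at least 1. Differences of age slopes were tested between species within a region and between regions within a species, the second with the animal as a block. Standard errors of log2 slopes were derived from the F statistic, and intervals of folds are 95% intervals from them. CPM values are counts scaled to a common library total with TMM factors over all libraries. Agreement of age slopes was measured across genes with least-squares slopes on log2 CPM with a prior count of 2, and was set against 100 random orders of the ages within species and sex, one-sided, for which the smallest possible p is 0.0099. The tests, their samples and covariates, the rule for named genes and the main list of alternatives were fixed before the data were examined.

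The pairing of regions comes from the animal given in the labels. Same-animal libraries deviated together from their group means, with a median correlation across genes of 0.19 in African green monkeys (range -0.047 to 0.44) and 0.26 in macaques (range 0.039 to 0.43), against -0.0038 and -0.011 for different animals. The visual cortex library correlated best with the prefrontal library of its own animal in 12 of 19 and 21 of 25 animals.

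The rule for named genes asked for gene symbols, which the files do not give. Its other parts were kept: IDs past the threshold with a mean of at least 1 CPM, ordered by p for age and interactions and by size of fold change for regions, and the first 2 in each direction are given per comparison. Where fewer than 5 genes passed, the IDs with the smallest p are given with their adjusted p. The 44 gene lists fixed in advance, the planned check of named sex genes and the oligodendrocyte covariate need symbols and were not run. A check without names was added after the results had been seen. It took the genes whose lowest CPM in one sex (at least 1) exceeded 10 times the highest in the other over all African green monkey libraries, and counted in each macaque library how many were at the male level. As 1 macaque did not match its labelled sex, the macaque results were also run with it taken as male and without it. The labels were kept as given in the main fits, which were fixed in advance.

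Alternatives were DESeq2 1.42.0 size factors and its Wald test, no low-count filter, limma 3.58.1 voom with quality weights, limma on log2(FPKM + 0.1) and log2(FPKM + 1) for genes with a mean FPKM of at least 0.1, log2 of age, no sex covariate, 1 surrogate variable from sva 3.50.0, subsets by age, and no block. A fold change on the FPKM scale understates the change of low genes. Alternatives added after the data were seen were the omission of each library in turn, of 6 libraries whose root mean square log2 distance from the mean of their group exceeded 0.5, and of 3 macaque visual cortex libraries with a region score under 0.7, and the addition of log2 total count and the share of counts of the 10 most abundant genes as covariates. The region score projects a library on the line from the prefrontal mean (0) to the visual cortex mean (1) of the other animals of its species. The sum of both regions of each animal, and a limma comparison between species of each animal's log2 CPM difference between regions, were also added then.

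Each count of calls was set against other orders of the ages, or of the regions within animals, with 100 orders for age and for species by age, and 40 for region and for region by age, the real one included. The region effect between species was first tested with edgeR, and limma on the differences was made its main test after that result had been seen, because it allowed 100 orders within the time. The tests were checked on simulated counts with the real means, library sizes and dispersions and 200 changed genes per comparison. In the 4 age tests, on 13080 to 13995 genes, 76% to 84% of simulated slopes of log2 0.5 and 96% to 99% of those of log2 1 were recovered, and false calls made up 2.17% to 6.42% of calls. In the region tests the recovery was 80% and 93% for log2 0.5. It was 60% and 67% for differences of slopes of log2 0.5 between species, and 68% and 79% for those between regions. Genes were simulated independently of each other, so shifts common to many genes of a library were not covered. In the real data 1 other order of ages called 2773 genes in the African green monkey prefrontal cortex. Changes under log2 0.5 were not simulated, while the median size of the called age slopes was 0.245 to 0.47 in the 4 groups. Plots were drawn with matplotlib 3.10.9.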

Results

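The transcriptome was examined with age in the prefrontal cortex and the visual cortex of 2 monkey species. The 19 African green monkeys (12 females and 7 males) were 364 to 1664 weeks old, with a median of 780 weeks. The 25 rhesus macaques (labelled as 14 females and 11 males) were 132 to 1584 weeks old, with a median of 400 weeks. Every animal gave 1 library from each region. Total counts per library had a median of 3875218 in the African green monkey prefrontal cortex and 4424263 in its visual cortex, and of 6294885 and 5215370 in the macaque regions. The lowest total per group was 3286729, 2952084, 2530226 and 1089960, in the same order. Genes are named by the IDs of the deposited tables, which are not paired with gene names.

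The labelled sex of 1 macaque did not match its expression. In African green monkeys 10 genes separated all males from all females in both regions by more than 10 times, 9 of them higher in males. In macaques all 10 were at the level of the labelled sex in every other library, but at the male level in both libraries of 1 animal labelled female (1256 weeks, prefrontal replicate 8 and visual cortex replicate 9). ENSG00000114374 was at 187 and 192 CPM in these libraries, against at most 2.09 CPM in the other macaque females and at least 158 CPM in the macaque males. Its visual cortex library correlated at 0.411 with its own prefrontal library and at most at 0.204 with that of another animal. The sources do not tell whether only its sex or the animal itself was mislabelled, so its age is uncertain too. The fits below use sex and age as labelled. Counts of macaque age calls are also given with this animal taken as male and with it left out, while the orders of ages were not rerun without it.

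In the prefrontal cortex of African green monkeys, 30 genes rose and 33 fell with age, of 13080 tested. ENSG00000105419 fell by 0.95 on the log2 scale per 10 years (SE 0.11, adjusted p = 0.000127, edgeR), from 13.7 CPM in the youngest animals to 4.3 CPM in the oldest. The SDs of these means were 2.91 and 0.654 over 5 animals each. The 5 youngest African green monkeys were 4 females and 1 male and the 5 oldest 2 females and 3 males. Such means in either region therefore differ in sex as well as age. ENSG00000130558, an abundant transcript at 747 ± 134 CPM (SD, n = 19), fell by 0.30 (SE 0.050, adjusted p = 0.0134). ENSG00000182718 rose by 0.93 (SE 0.16, adjusted p = 0.0134) and ENSG00000147606 by 0.97 (SE 0.17, adjusted p = 0.0147), or 1.91-fold (95% interval 1.54 to 2.35) and 1.95-fold (1.56 to 2.45) per 10 years. ENSG00000182718 did not pass with limma on log2(FPKM + 0.1), where its slope was 0.82 and its adjusted p 0.0936, or on log2(FPKM + 1), with 0.70 and 0.0689. The number of called genes was 1777 without replicate 1 and 111 without replicate 11, and it was 8, 9, 11, 11, 15, 16, 22, 38, 40 and 41 without replicates 2, 18, 16, 17, 12, 7, 6, 4, 8 and 3. Replicates 1 and 18 stood farther from their group mean than any other African green monkey library (root mean square log2 distances of 0.695 and 0.58), and 938 genes were called without both. The count was also 1599 with limma voom, 265 with DESeq2, 120 with 1 surrogate variable, 24 on log2 of age, and 9 and 7 with limma on FPKM.

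In the visual cortex of African green monkeys, 209 genes rose and 282 fell with age, of 13280 tested. ENSG00000139318 fell by 0.73 on the log2 scale per 10 years (SE 0.068, adjusted p = 6.3e-07, edgeR), from 35.7 ± 5.06 CPM (SD) in the 5 youngest animals to 13.9 ± 1.76 CPM in the 5 oldest. ENSG00000171208 fell by 0.34 (SE 0.041, adjusted p = 7.81e-05), at a mean of 81.7 ± 15.2 CPM (SD, n = 19). ENSG00000185100 rose by 0.64 (SE 0.10, adjusted p = 0.00202) and ENSG00000096060 by 0.60 (SE 0.10, adjusted p = 0.00389). The share of counts of the 10 most abundant genes correlated with age in these libraries before adjustment (Pearson r = 0.496, permutation p = 0.031, Spearman rho = 0.463, permutation p = 0.0472), but r was 0.309 without the 2 animals farthest from the median age, and the values adjusted over the 12 relations examined were 0.372 and 0.462. With that share and the total count as covariates, 151 genes were called, and only 86 of them were among the genes called without these covariates. Without replicates 2, 5, 6, 15, 16, 17 and 18 in turn, 294, 990, 268, 308, 191, 210 and 164 genes were called, and the count was 829 with DESeq2, 895 with limma voom, 805 with 1 surrogate variable, 315 with no low-count filter, 140 on log2 of age, and 37 and 65 with limma on FPKM.

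In the prefrontal cortex of macaques, 180 genes rose and 272 fell with age, of 13995 tested. Of the 10 genes that separate the sexes, 5 were among the rising calls, with slopes up to 2.50 for ENSG00000114374, and 0 were called with the animal of unmatched sex taken as male, where 710 genes were called, or without it, where 235 were. ENSG00000110723 fell by 0.61 on the log2 scale per 10 years (SE 0.087), from 48.2 ± 8.64 CPM (SD) in the 5 youngest animals to 23.1 ± 8.17 CPM in the 5 oldest. ENSG00000134247 fell by 0.41 (SE 0.060). ENSG00000058866 rose by 0.60 (SE 0.088), from 51.2 ± 16.2 CPM to 103 ± 38.2 CPM in the same animals, and ENSG00000079931 rose by 0.50 (SE 0.077). All 4 had an adjusted p of 0.000687 (edgeR). With the 14 macaques of at least 364 weeks, the lowest African green monkey age, 21 genes were called. ENSG00000058866 kept a slope of 0.59 there but did not pass (adjusted p = 0.0519), and ENSG00000134247 had a slope of -0.29 (adjusted p = 0.122). Age and sex were partly confounded in macaques: the 5 oldest, of 864 weeks or more, were all labelled female, the animal of unmatched sex and uncertain age among them, no labelled male was over 740 weeks, and of the 5 youngest 4 were male in the prefrontal and 3 in the visual cortex set. The means of these animals therefore differ in sex as well as age, while the slopes were fitted with sex as a covariate. The count was 262, 272, 235, 868 and 788 without replicates 3, 4, 8, 19 and 21 in turn, of which replicate 19 was the oldest animal and replicate 21 stood farthest from the group mean (distance 0.658). It was 189 with total count and the share of the 10 most abundant genes as covariates, 795 without the sex covariate, 710 with DESeq2, 851 with limma voom, 826 on log2 of age, 888 with 1 surrogate variable, and 192 and 210 with limma on FPKM.

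In the visual cortex of macaques, 245 genes rose and 228 fell with age, of 13415 tested. With the animal of unmatched sex taken as male 873 genes were called, and without it (replicate 9) 103, and the 4 genes named here passed in both. ENSG00000114374, which separates the sexes, was among the rising calls (slope 2.35) and was not called in either setting. Of the 10 sex-separating genes 1 other was called with the animal taken as male (slope 0.30, adjusted p = 0.0332), and 0 without it. ENSG00000105419, which also fell in the African green monkey prefrontal cortex, fell by 0.80 on the log2 scale per 10 years (SE 0.11, adjusted p = 0.000174, edgeR), from 16.1 ± 3.13 CPM (SD) in the 5 youngest animals to 5.1 ± 1.97 CPM in the 5 oldest. ENSG00000176871 fell by 0.29 (SE 0.039, adjusted p = 0.000174), at a mean of 233 ± 36.6 CPM (SD, n = 25). ENSG00000148826 rose by 1.03 (SE 0.15) and ENSG00000172817 by 0.59 (SE 0.086), both with an adjusted p of 0.000601. Of these libraries, 3 had a region score between those of the regions: replicate 9 at 0.418 (1256 weeks), replicate 10 at 0.469 (144 weeks) and replicate 16 at 0.628 (1152 weeks). Without these 3, 50 genes were called. Without replicates 8, 9 and 18 in turn, 293, 103 and 881 were called, and replicate 18 was the oldest animal. With macaques of at least 364 weeks, edgeR called 0 genes and all 4 named genes lost their call, with slopes of -0.71 for ENSG00000105419, -0.24 for ENSG00000176871, 1.04 for ENSG00000148826 and 0.65 for ENSG00000172817. The count was 98 without the 3 libraries that stood apart (replicates 6, 9 and 22), 223 with total count and top share as covariates, 820 without the sex covariate, 727 with DESeq2, 244 with limma voom, 283 on log2 of age, and 107 and 114 with limma on FPKM.

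**Figure D1:**
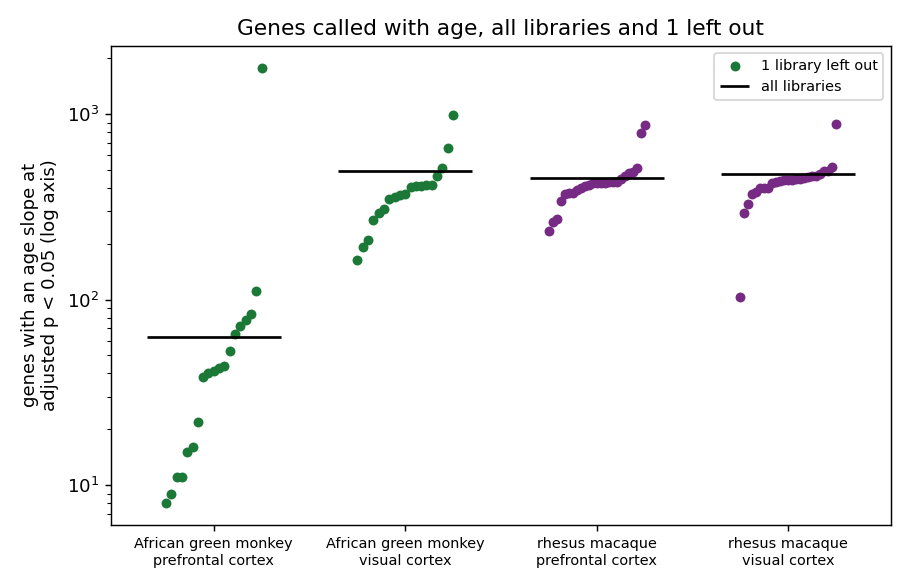
Number of genes called with age (adjusted p under 0.05, log axis) in the 4 groups with all libraries (line) and with each library left out in turn (points, green for African green monkey and purple for macaque). In the African green monkey prefrontal cortex the points run from 8 to 1777 around the value of 63.

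Some genes changed with age in every group. Of 12496 genes tested in all 4 groups, 1 rose and 5 fell in each of the 4 fits, and 9 rose and 27 fell in at least 3. ENSG00000096060 rose by 0.68 and 0.60 in the prefrontal and visual cortex of African green monkeys and by 1.02 in both macaque regions. ENSG00000105419 had slopes of -0.95 and -0.55 in African green monkeys and of -0.88 and -0.80 in macaques. ENSG00000130558, also among the 5, went from 857 CPM in the 5 youngest to 570 CPM in the 5 oldest African green monkeys in the prefrontal cortex (SD 72.3 and 56.4) and from 684 to 572 CPM in the visual cortex (SD 39.4 and 31.5). In macaques it went from 1040 to 662 CPM (SD 134 and 93) and from 771 to 490 CPM (SD 137 and 44.8). Calls shared between the species outnumbered the product of the shares of calls. In the visual cortex 23 rising and 33 falling genes were shared, against 3.76 and 4.89 from that product, while 1 that rose in African green monkeys fell in macaques and 1 did the opposite, and in the prefrontal cortex 3 and 16, against 0.393 and 0.641. Within an animal the regions are not independent, so the 39 rising and 69 falling genes shared by the macaque regions (3.19 and 4.49 from the product) and the 8 and 14 shared by the African green monkey regions (0.442 and 0.721) include chance values common to both libraries of an animal. With the macaque of unmatched sex taken as male, 32 rising and 54 falling genes were shared between the species in the visual cortex, 4 and 21 in the prefrontal cortex, and 70 and 131 between the macaque regions. Without this animal the counts were 7 and 13, 2 and 13, and 6 and 21, against 0.705 and 1.23, 0.19 and 0.332, and 0.294 and 0.6 from the product. In all 4 fits 1 rose and 7 fell with it taken as male, and 1 rose and 3 fell without it, the 3 genes named here among them.

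**Figure D2:**
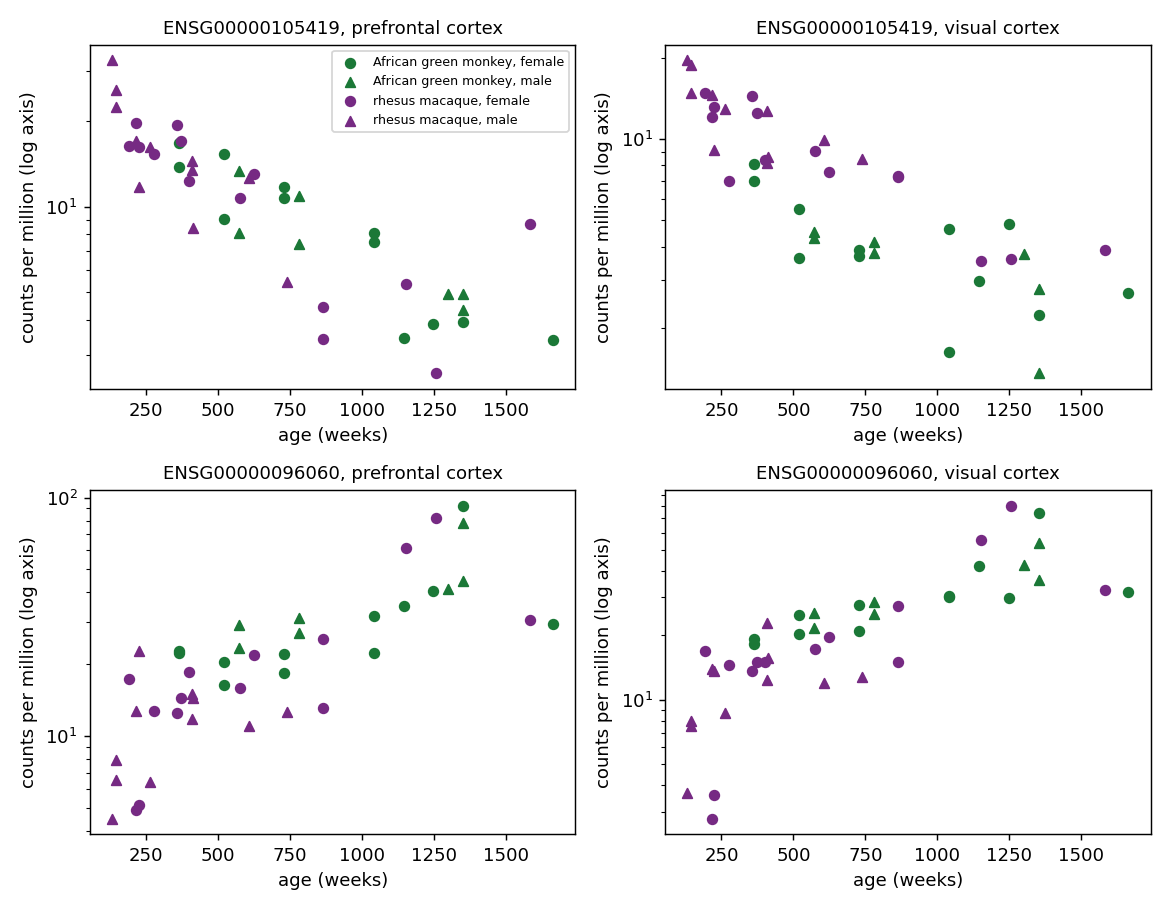
CPM (log axis) against age in weeks for the genes called in all 4 groups with the lowest and the highest mean slope, ENSG00000105419 and ENSG00000096060. Each point is 1 library, coloured by species and shaped by labelled sex, and levels of different species were sequenced in different batches.

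The visual cortex differed from the prefrontal cortex in a large part of the genes tested in both species. In African green monkeys 3039 genes were higher and 2779 lower in the visual cortex, of 12941 tested, and 155 and 209 of them changed by at least 1 on the log2 scale. In macaques 4084 were higher and 4181 lower, of 13847 tested, and 179 and 373 reached that size. Without the macaque of unmatched sex 4211 were higher and 4183 lower, of 13859 tested. ENSG00000188729 was at 10.7 ± 6.07 CPM (SD, n = 19) in the visual cortex and 0.253 ± 0.333 CPM in the prefrontal cortex of African green monkeys, and at 11.5 ± 5.04 and 0.722 ± 0.484 CPM (SD, n = 25) in macaques. ENSG00000169435 was at 4.34 ± 1.56 and 0.111 ± 0.178 CPM in African green monkeys, and at 5.29 ± 3.3 and 0.329 ± 0.283 CPM in macaques. ENSG00000186188 was lower in the visual cortex, at 0.0464 ± 0.119 against 4.93 ± 1.42 CPM in African green monkeys and 0.068 ± 0.207 against 2.83 ± 1.12 CPM in macaques. ENSG00000152034 was at 0.473 ± 0.39 against 9.1 ± 1.54 CPM in African green monkeys, and ENSG00000133710 at 0.282 ± 0.712 against 6.87 ± 6.51 CPM in macaques. Each of these genes differed in its direction in 19 of 19 or 25 of 25 animals, and their adjusted p values (edgeR, animal as a block) ran from 4.04e-12 to 2.09e-18. The low side rested on few reads, 4 counts over the 19 African green monkey visual cortex libraries for ENSG00000186188, so no fold is given. Of genes at that size in both species, 79 were higher and 134 lower in both, against 1.78 and 4.52 from the product of shares, and 1 was opposite. Across the 12699 genes tested in both species, the region differences correlated at a Pearson r of 0.761 (Spearman 0.71), a correlation over genes, which are not independent replicates.

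**Figure D3:**
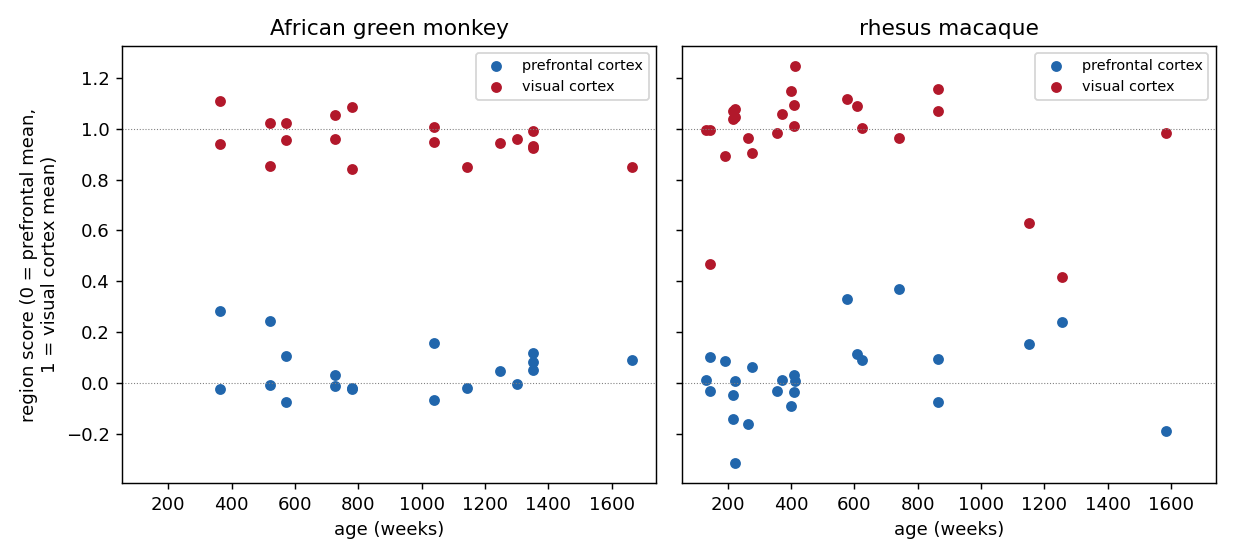
Region score of each library against age in weeks, by species, with the prefrontal mean at 0 and the visual cortex mean at 1. The scores of 3 macaque visual cortex libraries, 0.418, 0.469 and 0.628, lie between those of the regions.

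Few genes passed the test of a difference of age slopes between the species. At an unadjusted p under 0.05 (edgeR) there were 1453 genes in the prefrontal and 1833 in the visual cortex. Simulated differences of log2 0.5 were recovered at 60% and 67%, and those of log2 1 at 89% and 96%. The low counts therefore do not show that few slopes differ by log2 0.5 or less. In the prefrontal cortex 1 gene of 13498 passed, ENSG00000131389, with a slope of 0.36 per 10 years in African green monkeys (SE 0.083) and -0.18 in macaques (SE 0.060), a difference of -0.55 (SE 0.10, adjusted p = 0.0324, edgeR). ENSG00000140403 (difference 0.42, adjusted p = 0.0951), ENSG00000189221 (0.40, adjusted p = 0.128) and ENSG00000120162 (-0.66, adjusted p = 0.0951) came next and did not pass, though ENSG00000140403 (adjusted p = 0.0293) and ENSG00000120162 (adjusted p = 0.0361) did without the sex covariate. In the visual cortex the slope was higher in macaques for 6 genes and lower for 6, of 13369 tested. ENSG00000129422 fell by 0.28 in African green monkeys and rose by 0.27 in macaques (difference 0.55, SE 0.090, adjusted p = 0.00176). ENSG00000172817 had slopes of -0.072 and 0.59 (difference 0.66, SE 0.12, adjusted p = 0.00694). ENSG00000115155 had slopes of 0.37 and -0.81 (difference -1.19, SE 0.23), and ENSG00000185100 of 0.64 and -0.079 (difference -0.72, SE 0.14), both with an adjusted p of 0.0189. With macaques of at least 364 weeks the counts were 1 in the visual and 0 in the prefrontal cortex, where ENSG00000131389 kept a difference of -0.54 (adjusted p = 0.137). In the visual cortex ENSG00000129422 passed and the other 3 named genes did not, though their differences stayed about as large (0.72 for ENSG00000172817, -0.97 for ENSG00000115155 and -0.76 for ENSG00000185100), while without the oldest animal of each species 121 genes passed in the visual cortex. The prefrontal count was 23 without the libraries that stood apart, 8 with limma voom and 3 without the sex covariate, and the visual cortex count was 5 on log2 of age, where ENSG00000172817 did not pass (0.43 per doubling of age, adjusted p = 0.193). With the macaque of unmatched sex taken as male the counts were 2 and 40, and ENSG00000140403 passed (adjusted p = 0.041), while without it they were 0 and 13, and ENSG00000131389 did not pass (difference -0.55, adjusted p = 0.0601). Of these 13 visual cortex genes, 7 were among those called with all libraries. Without the 3 visual cortex libraries of low region score 12 genes passed there, and 6 of them were among those called with all libraries.

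The test of a difference of age slopes between the regions called 18 genes in macaques, of 13847 tested. The slope was higher in the visual cortex for 14 and lower for 4. Chance was not excluded for this count, since 2 of 40 orders of ages, the real one included, reached it. ENSG00000079819 had a slope of -0.40 in the prefrontal and -0.10 in the visual cortex (difference 0.28, SE 0.050), and ENSG00000080200 of -0.25 and 0.40 (difference 0.59, SE 0.11). ENSG00000113805 had slopes of 0.13 and -0.23 (difference -0.36, SE 0.064), and ENSG00000177106 a difference of -1.12 (SE 0.21). All 4 had an adjusted p of 0.0176 (edgeR, animal as a block). No gene passed without the 3 visual cortex libraries of low region score or with limma voom, where all 4 lost their call. Without those libraries the differences of the 4 stayed at 0.28, 0.59, -0.37 and -1.11, in the order given, and the adjusted p was 0.153 for each. With no block 3 genes passed, and ENSG00000079819, ENSG00000113805 and ENSG00000177106 did not (adjusted p = 0.226, 0.151 and 0.127). On log2 of age 5 passed, and ENSG00000079819 and ENSG00000177106 did not (adjusted p = 0.164 and 0.0946). Without the libraries that stood apart ENSG00000080200 did not pass (0.55, adjusted p = 0.0579). Without the oldest macaque 12 genes passed, 5 of them among the 18, and ENSG00000079819 (0.22, adjusted p = 0.109), ENSG00000113805 (-0.32, adjusted p = 0.082) and ENSG00000177106 (-0.92, adjusted p = 0.11) did not. Without the animal of unmatched sex 2 genes passed, and ENSG00000079819 (0.29, adjusted p = 0.0558) and ENSG00000080200 (0.55, adjusted p = 0.104) did not. In African green monkeys edgeR called 0 of 12941 genes, with 1624 at an unadjusted p under 0.05. The smallest p belonged to ENSG00000159674 and ENSG00000091592 (differences 1.53 and 0.52) and to ENSG00000164309 and ENSG00000172020 (-0.56 and -0.38), all with an adjusted p of 0.391. Limma voom called 2467 genes in the same libraries, all 4 of these IDs among them, and edgeR called 5 without the animals of prefrontal replicates 1 and 18.

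Genes called with age in one species tended to have the same sign in the other. In the visual cortex, 409 of the 482 genes called in African green monkeys and tested in macaques had the same sign there (84.9%, against a median of 52.6% over 100 orders of macaque ages, permutation p = 0.0099, the smallest possible). This share did not pass in 3 other settings: it was 75.5% without the libraries that stood apart (permutation p = 0.129), 80.5% without the oldest animal of each species (permutation p = 0.0594) and 77% with macaques of at least 364 weeks (permutation p = 0.109). Of 461 genes called in macaques, 369 had the same sign in African green monkeys (80%, against 47.3% over 100 orders of African green monkey ages, permutation p = 0.0198). In the prefrontal cortex the shares were 47 of 61 (77%, permutation p = 0.129) and 344 of 431 (79.8%, permutation p = 0.0099). Without the macaque of unmatched sex the shares of macaque calls were 90 of 101 in the visual cortex (89.1%, permutation p = 0.0099) and 174 of 217 in the prefrontal cortex (80.2%, permutation p = 0.0198). Across all genes tested in both species the slopes correlated at r = 0.268 in the visual cortex (12767 genes, permutation p = 0.0297) and r = 0.245 in the prefrontal cortex (12835 genes, permutation p = 0.0792) when macaque ages were permuted, and both had a permutation p of 0.0099 when African green monkey ages were permuted. The Spearman values were 0.218 and 0.24 (permutation p = 0.109 and 0.129 with macaque ages permuted, and 0.0297 and 0.0099 with African green monkey ages permuted). The visual cortex value did not pass without the oldest animal of each species (r = 0.24, permutation p = 0.0792), without the libraries that stood apart (r = 0.193, permutation p = 0.158) or without the macaque of unmatched sex (r = 0.239, permutation p = 0.0693). The prefrontal value passed in those settings (r = 0.299, 0.249 and 0.231, permutation p = 0.0495, 0.0297 and 0.0495) and on log2 of age (r = 0.338, permutation p = 0.0297), and it was 0.00778 with macaques of at least 364 weeks (permutation p = 0.505). Its Spearman value did not pass without the libraries that stood apart or without the macaque of unmatched sex (permutation p = 0.129 and 0.0891). With that macaque taken as male, r was 0.218 in the prefrontal cortex and did not pass (permutation p = 0.158). In the visual cortex r was then 0.29 (permutation p = 0.0198, and 0.099 for Spearman). The visual cortex value also passed on log2 of age (r = 0.273, permutation p = 0.0099).

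**Figure D4:**
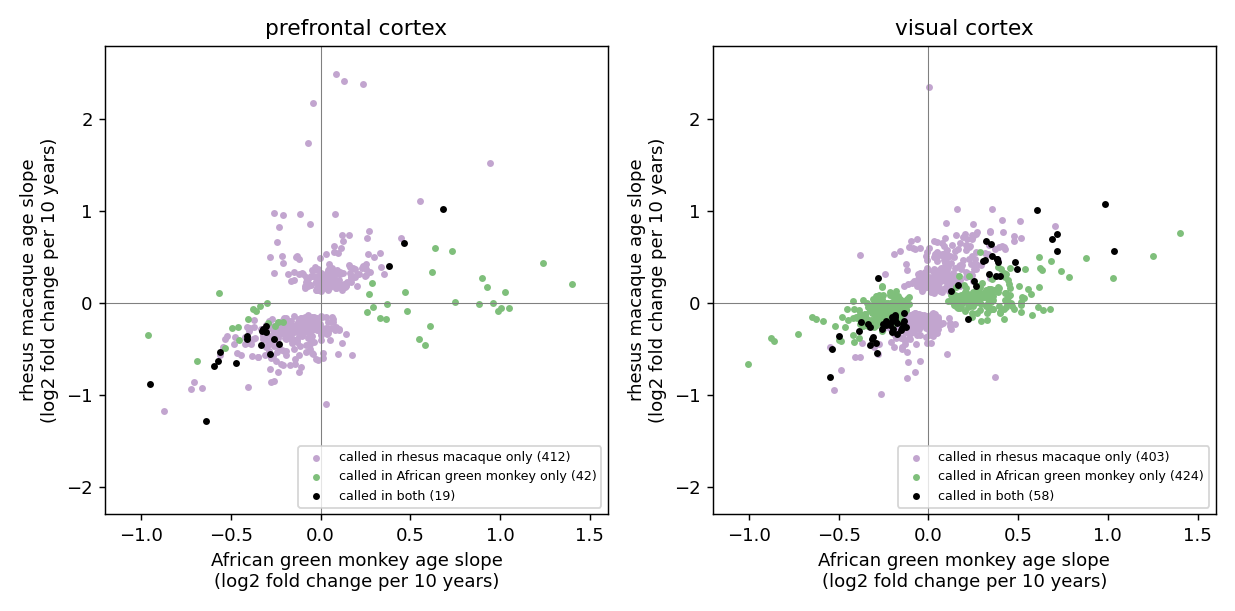
Age slope per gene in African green monkeys (horizontal) and macaques (vertical), as log2 fold change per 10 years, for genes called in at least 1 species, by region. Genes called in both species are black. In the visual cortex 33 falling and 23 rising genes were shared, and 1 of each direction in African green monkeys was called with the opposite sign in macaques. Macaque slopes are with animals as labelled. The highest in each region, 2.50 and 2.35, is that of ENSG00000114374, which separates the sexes and was not called with the animal of unmatched sex taken as male or left out.

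Between the regions of the same macaques the slopes correlated at r = 0.521 across 13300 genes (Spearman 0.466). The median over 100 orders of age, applied alike to both regions, was 0.214, and none reached the observed value (permutation p = 0.0099, the smallest possible). The covariance was 0.0109 against a median of 0.00205 in those orders. In African green monkeys r was 0.272 across 12855 genes (Spearman 0.126), against a median of 0.156 over the orders of age (permutation p = 0.218).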

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

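The test of the region effect between species was chosen after results had been seen, as was the omission of libraries and of 1 macaque in this part. In 4 comparisons a test of the difference itself had genes past its threshold. For the age slope between the species, 1 gene passed in the prefrontal cortex and 12 genes in the visual cortex. Between the regions of macaques 18 genes passed. Without 1 macaque whose expression did not match its labelled sex these counts were 0, 13 and 2, and only 7 of the 13 were among the 12. Chance was not excluded for the 1 gene and the 18 genes, and for the 12 genes the orders of ages cannot decide whether slopes are equal, as given below. The difference between visual and prefrontal cortex itself differed between the species for 2364 of 14169 genes (16.7%, limma on the difference of log2 CPM per animal, adjusted p under 0.05). Of these, 1200 were higher and 1164 lower in macaques, 188 differed by at least 1 on the log2 scale, and 177 were called in both species with opposite signs. Regions were compared within each batch, but the labels name the prefrontal region differently in the species. The test held no age or sex term, and the median age was 780 weeks in African green monkeys and 400 weeks in macaques. A batch effect that differs between the regions would not cancel either. A species difference, such a batch effect, a difference of the dissected area and differences of age or sex therefore cannot be told apart.

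With all animals as labelled, a share under 0.05 of the orders of ages, regions or species reached most counts, with no adjustment over the counts. Chance is argued against for these, but only weakly where 2 of 100 orders reached the count. Orders with at least as many calls, the real one included, numbered 1 of 100 for age in the macaque prefrontal cortex (real 452, highest other 26) and visual cortex (473, 237), and 2 of 100 in the African green monkey visual cortex (491, 844). In that group the next highest order called 475. With 1 library left out its count fell as low as 164, under both orders, so chance is not shown to be excluded for such counts. The macaque orders kept the animal of unmatched sex and uncertain age and were not rerun without it. Without it 103 genes were called in the macaque visual cortex, under the 237 of 1 order, so chance is not shown to be excluded for that count. In the African green monkey prefrontal cortex 2 of 100 orders reached the real count of 63, and the highest other called 2773, many times the real count. This points to a structure of the samples, which was not tested and rests on 1 order, since the next highest called 15. For regions 1 of 40 orders reached it in African green monkeys (5818, 1002) and in macaques (8265, 0). For the species by age comparison it was 2 of 100 in the visual cortex (12, 32). Ages were permuted within both species there, which removed the age slopes themselves, so these orders cannot decide whether the slopes are equal. Chance was not excluded for the prefrontal cortex, with 11 of 100 (1, 6). It was not excluded for region by age in macaques either, with 2 of 40 (18, 25). In African green monkeys the real order called 0 genes, so 40 of 40 orders had to reach it and nothing could be decided. For the region effect between species 1 of 100 orders reached the real count (2364, 660).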

How the results depend on the processing

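The omission of each library or animal in turn, of those that stood apart or had a low region score and of 1 macaque, the change of its sex label, the covariates of depth and top share, and the tests on summed regions and between species of the region effect were chosen after results had been seen, while the settings without the oldest animals and with macaques of at least 364 weeks were planned, except on summed regions. Of 141 counts and correlations under other settings, 73 kept their side of the threshold or stayed within 1.5 times, 61 counts moved further, 3 correlations lost and 4 gained their call, and 0 reversed. Of 779 values of named IDs, 737 kept their side of the threshold, 33 lost their call, 19 of them for region by age in macaques, and 9 gained one, 5 for species by age in the prefrontal cortex and 4 for region by age in African green monkeys. None reversed. Leaving out 1 library gave 8 to 1777 age calls in the African green monkey prefrontal cortex (63 with all), 164 to 990 in its visual cortex (491), 235 to 868 in the macaque prefrontal cortex (452) and 103 to 881 in its visual cortex (473). With regions summed the ranges were 178 to 724 (461) and 252 to 1304 (671). In the same order of 4 groups, DESeq2 gave 265, 829, 710 and 727, limma voom 1599, 895, 851 and 244, log2 of age 24, 140, 826 and 283, log2(FPKM + 0.1) 9, 37, 192 and 107, and log2(FPKM + 1) 7, 65, 210 and 114. With 1 surrogate variable the first 3 gave 120, 805 and 888, and with depth and top share as covariates the last 3 gave 151, 189 and 223. No filter gave 315 in the African green monkey visual cortex. In macaques (prefrontal, visual) the counts were 868 and 881 without the oldest animal, 795 and 820 without sex, and 21 and 0 at 364 weeks or more. Without libraries that stood apart the counts were 938 in the African green monkey prefrontal cortex and 788 and 98 in the macaque regions, and without low region scores 50 in the macaque visual cortex. Species by age in the prefrontal cortex (1) gave 8 with voom, 3 without sex, 0 at 364 weeks or more and 23 without libraries that stood apart, and in the visual cortex (12) 5 on log2 of age, 121 without the oldest animals and 1 at 364 weeks or more. Region by age gave 2467 with voom and 5 without animals that stood apart in African green monkeys (0), and 0 with voom, 5 on log2 of age and 0 without low region scores in macaques (18). Slope agreement between species gained its call in the prefrontal cortex without the oldest animals (0.299), on log2 of age (0.338) and without libraries that stood apart (0.249), and lost it in the visual cortex without the oldest animals (0.24) and without libraries that stood apart (0.193). With the macaque of unmatched sex taken as male, age gave 710 in the prefrontal and 873 in the visual cortex and 1092 with regions summed, and species by age gave 2 and 40. Without this animal, age gave 235 and 103, species by age 0 in the prefrontal cortex and region by age in macaques 2, and slope agreement was 0.231 in the prefrontal cortex, which passed, and 0.239 in the visual cortex, which did not. With regions summed, 222 genes were called without the African green monkeys that stood apart and 173 in macaques of at least 364 weeks. With no block for the animal the region counts were 5758 and 7888, with 5555 of the 5818 and 7797 of the 8265 calls kept, and region by age gave 3 in macaques and stayed at 0 in African green monkeys. Subsets by age hold fewer animals, and for the other changes the cause was not tested. The gene lists with their fry, estimated correlation and unblocked alternatives, and the oligodendrocyte covariate, were not run. Depth limits low genes: at the lowest total of 1089960 counts, 1 CPM is about 1 count.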

Other observations

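The sums of regions, the omission of single animals, the check of sex, the tests of causes of the slope agreement, and those on African green monkey prefrontal replicate 1 and on the region scores were chosen after results had been seen. The slope agreement itself, its setting with macaques of at least 364 weeks and its orders of ages were planned, though their reading as tests of a cause was set afterwards. The depth and slope tests on the African green monkey prefrontal cortex were set first. With both regions of each animal summed, 209 genes rose and 252 fell with age in African green monkeys (461 of 14626, edgeR), and 287 rose and 384 fell in macaques (671 of 15171). The species shared 26 rising genes, against 3.94 from the product of the shares, and 90 falling genes, against 6.64, and 0 were opposite. These were 36 and 119 with the macaque of unmatched sex taken as male, and 10 and 46 without it. Of 100 orders of age, 1 reached the count in African green monkeys (461, highest other 78) and 1 in macaques (671, highest other 42), the real order included. Without the animal of replicate 1 the African green monkey count was 543, and it was 291, 238, 178, 267, 191 and 724 without those of replicates 2, 7, 16, 17, 18 and 19. The macaque count was 252, 440, 399, 1056 and 1304 without the animals of visual cortex replicates 9, 16, 8, 3 and 18, and 1092 with the animal of replicate 9, whose expression did not match its labelled sex, taken as male. Slopes of macaques under 364 weeks (n = 11) and of older ones (n = 14) correlated across genes at -0.146 in the prefrontal cortex (permutation p = 0.822) and 0.0907 in the visual cortex (permutation p = 0.168).

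Fewer genes were called with age in the prefrontal cortex of African green monkeys (63) than in the visual cortex (491). Lower depth is argued against, since visual cortex libraries thinned to the depth of the prefrontal library of the same animal still gave a median of 483 calls over 5 draws (451 to 500). Weaker slopes are argued against only for 106 genes called in the same direction in both macaque regions. Their median African green monkey slope in that direction was 0.0849 higher in the prefrontal than in the visual cortex (jackknife 95% interval -0.0178 to 0.188). Weaker slopes over other genes, such as those called in African green monkeys only, were not tested. That prefrontal replicate 1 widens the spread stays open as a candidate explanation, since 1777 genes were called without it. What sets this library apart was not tested, and no biological explanation was tested.

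Age slopes of the species correlated at 0.245 in the prefrontal and 0.268 in the visual cortex. A change of depth and of the share of the 10 most abundant genes with age is argued against as the main source in the visual cortex, where the correlation with both as covariates was 0.348, a fall of -0.0798 (jackknife 95% interval -0.212 to 0.0524), and so is a trend with transcript length and abundance, whose removal left 0.245 (permutation p = 0.0297 as before), a fall of 0.0232 (interval -0.00092 to 0.0473). Chance stays open in both regions, since 7 of 100 orders of macaque ages in the prefrontal and 2 of 100 in the visual cortex gave a correlation as large, and the Spearman value of the visual cortex had a permutation p of 0.109. Growth of young macaques stays open in the prefrontal cortex, where the correlation was 0.00778 with those of at least 364 weeks, though it had not passed with all animals. In the visual cortex the Pearson value was 0.257 with those animals (permutation p = 0.0495), so it stayed near its size without the young macaques. The share of African green monkey calls with the same sign there fell from 84.9% to 77% (permutation p = 0.0099 and 0.109). Those animals also include the macaque of uncertain age. Growth is therefore not decided in the visual cortex, and chance stays open as well. The Spearman value of the visual cortex did not pass with those animals (permutation p = 0.149), but it had not passed with all animals either and cannot decide. Shared ageing of the species remains an untested explanation.

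In 3 macaque visual cortex libraries the region score lay between the regions (replicate 9 at 0.418, replicate 10 at 0.469 and replicate 16 at 0.628). Low depth is argued against, since the 5 macaque visual cortex libraries with fewer counts than each of these scored at least 0.9824. For a mixture with prefrontal tissue, the share estimated from genes higher in the visual cortex and that from genes higher in the prefrontal cortex should be equal, and their difference ran from -0.137 to 0.186 in the other 22 libraries. It was 0.587 for replicate 9 and 0.37 for replicate 16, which argues against such a mixture or a swap as the whole cause, and 0.122 for replicate 10, where a mixture could account for the score. The prefrontal libraries of the same animals scored 0.238, -0.0338 and 0.152, so none is out of place, while the labelled sex of replicate 9 did not match its expression in either region, which leaves its identity and age uncertain, and a different part of the visual cortex was not tested as a biological explanation.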
